A study of Mus musculus with 6 samples.

How the data were processed

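Small RNA libraries were made from the testes of C57BL/6 mice whose scrotum had been held for 15 minutes in a water bath at 43 °C (heat stress) or at 36 °C (control), and tissue was taken 24 hours later. Per the labels, 12 mice were divided between the groups and 6 libraries were sequenced, 3 per group. The labels do not say whether a library came from 1 mouse or from several, so p-values measure the spread between these libraries. Total RNA was extracted with Trizol and libraries followed a standard Illumina protocol, per the labels' protocols. The adapter trimming, length selection, aligner, piRNA database and genome build are not given in the sources used here.

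Each library has 1 file, with 1 value for each of 659239 small RNA species. Of these species, 24845 carry identifiers of the form mmu_piR_ followed by a number. The other 634394 carry identifiers of the form uniq_ followed by a number, which the files do not define. The deposited values are RPM, reads scaled to a total of 1000000 per library, although the column is named tpm per the file headers: each library sums to this total over all listed species. In every library 100% of the values above 0 were whole multiples of the smallest value, within 0.001 of a read, so the number of reads behind each value was recovered. The recovered reads are those on the listed species, not all reads sequenced. No library pair within a group agreed within sampling noise: the chi-square per degree of freedom was 9.76 to 12.1 between controls and 24.4 to 65.1 between heat stress libraries. The files hold neither sequences nor lengths nor positions. The tests, the named-species rule, the lists and the first group of alternatives below were fixed before the data were examined. Of these, the comparisons of length classes, of the first base, of genomic windows and of host genes were not made, and none of the microRNA or host gene lists (markers of blood, muscle, endothelium, stroma, epithelium, Sertoli, Leydig, peritubular and germ cells and of macrophages, X-linked, proliferation, let-7 and stress microRNAs, heat shock and piRNA pathway genes) had a listed member, the count being 0. The shares by RNA class were reduced to the shares of the mmu_piR_ and uniq_ types.

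The main test was set by the unit: as the deposited values were RPM, limma 3.58.1 in R 4.3.3 was run on log2(RPM + 1) with a mean-variance trend and robust moderation, over the 50786 species with at least 1 RPM in at least 3 libraries, with no covariate. Fold changes from this fit are on the log2(RPM + 1) scale, which understates the change of low species. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The depth of heat stress replicate 3 was the lowest of the 6, and 1 of its reads is worth 1.72 RPM, against 0.235 to 0.442 RPM in the other libraries, so species of a few RPM are poorly measured there. Differences in single measures per library were tested with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Shares of a single library carry 95% Wilson intervals, and a count of 0 is read against a limit of 3 reads over the group; both cover counting error only. The number of distinct species at equal depth is the expected number among 582789 reads drawn without replacement.

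The species named were chosen by this rule: among species past the threshold with a mean of at least 10 RPM and no overlap between groups, the 10 with the largest rise and the 10 with the largest fall, and in addition the 5 with the highest mean over all libraries. The first group of alternatives was a pseudocount of 0.1, no filter, a filter of 10 RPM in 3 libraries, a minimum of 2-fold, the replicate number as a block, leaving out each library, edgeR 4.0.16 with other scalings and DESeq2 1.42.0, both tools on the recovered reads. Chosen after seeing the data were the use of the edgeR quasi-likelihood test with TMM scaling on the recovered reads, TMM and DESeq2 factors applied to the RPM values, array weights, scaling to the mmu_piR_ reads alone (mmu_piR_ species only), thinning of all libraries to 582789 reads, and the share of distinct species at that depth. This edgeR test had been fixed beforehand as the main test for files that hold counts, but with edgeR's default filter. The comparisons of species number, of the share of the most abundant species and of species found in 1 group only were also added after the data were seen.

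The fits were tested on simulated data for the comparison of heat stress with control, with counts for the 50786 species drawn at the libraries' depths. In a first version, 200 species of any abundance were changed 2-fold or 4-fold under the wider spread of the heat stress libraries, and limma and edgeR recovered 0 of them, while DESeq2 recovered 1% of the 2-fold and 7% of the 4-fold changes with 3 false calls. Of the species changed, 73 of 100 and 82 of 100 lay under 10 RPM. After this outcome the simulation, but no setting of the tests, was revised to an easier one, in which the 200 changed species had at least 10 RPM and the changes reached 16-fold. With the controls' spread in both groups, limma recovered 10% of the 2-fold, 94% of the 4-fold and 100% of the 8-fold and 16-fold changes, with 2 false calls. With the wider spread of the heat stress libraries it recovered 2%, 8%, 54% and 84%, with 4 false calls, against 7 for edgeR and 20 for DESeq2. These shares hold for species of at least 10 RPM only, while most of the tested species lie below. Only 200 of 50786 species were changed, by equal folds up and down, so the simulated libraries held no shift in composition. The false calls therefore do not cover falls that such a shift would give on the RPM scale.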

Results

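The study asked how a short exposure of the testis to elevated temperature alters its piRNAs, the small RNAs that are bound by PIWI proteins in male germ cells and silence transposons and other transcripts. Small RNA sequencing of testis was compared between 3 heat stress libraries and 3 control libraries. The reads on listed species numbered 3873540, 4255001 and 2573473 in control replicates 1, 2 and 3, and 2260175, 2599530 and 582789 in heat stress replicates 1, 2 and 3. The control libraries were alike: Pearson's r of log2(RPM + 1) across the 50786 tested species lay between 0.92 and 0.95 for the 3 control pairs. It lay between 0.82 and 0.86 for the 3 heat stress pairs and between 0.62 and 0.82 for pairs across the groups. Species are not independent replicates, so these coefficients describe the libraries only. Heat stress replicate 2 was the closest of its group to the controls, with r of 0.78 to 0.82, against 0.64 to 0.67 for replicate 1 and 0.62 to 0.65 for replicate 3. At 10747 species with a mean of at least 10 RPM, the median standard deviation between libraries was 0.84 on the log2 scale in heat stress and 0.23 in control.

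The first comparison concerned the 2 types of species in the files. Species with mmu_piR_ identifiers held a larger share of the reads after heat stress, 85.8% ± 7.85 (SD, n = 3) against 67.3% ± 0.0447 (SD, n = 3), a difference of 18.5 percentage points. The share was higher in each heat stress library than in every control library. It was 87.5% in replicate 1 (95% Wilson interval 87.5 to 87.6), 77.2% in replicate 2 (77.2 to 77.3) and 92.6% in replicate 3 (92.6 to 92.7). Species with uniq_ identifiers held the remainder, 14.2% ± 7.85 in heat stress and 32.7% ± 0.0447 in control. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

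Heat stress libraries also held fewer distinct small RNA species. At an equal depth of 582789 reads, 53342 ± 19125 species (SD, n = 3) were expected in heat stress and 94886 ± 790 (SD, n = 3) in control. The number was 45517, 75139 and 39371 in heat stress replicates 1, 2 and 3. The difference lay in the uniq_ species, with 36569 ± 18855 in heat stress and 78905 ± 618 in control (exact permutation p = 0.1). The mmu_piR_ species numbered 16773 ± 1032 in heat stress and 15981 ± 189.9 in control, a difference that did not exceed the spread between libraries (exact permutation p = 0.4). The depth was made equal over all listed reads, not within each type. Of these reads uniq_ species held 14.2% in heat stress and 32.7% in control. Their lower number thus partly restates that share and does not separately show a loss of diversity. The mmu_piR_ numbers likewise set a larger share of reads in heat stress against a smaller one in control. The 100 most abundant species of each library held 27.3% ± 6.33 of its reads in heat stress and 18.1% ± 0.567 in control (exact permutation p = 0.1, n = 3 per group). Of the 100 most abundant species of heat stress replicates 1, 2 and 3, 21, 59 and 23 were among the 100 most abundant in the mean of the controls. For the controls, each set against the mean of the other controls, this number was 83 to 87.

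**Figure D1:**
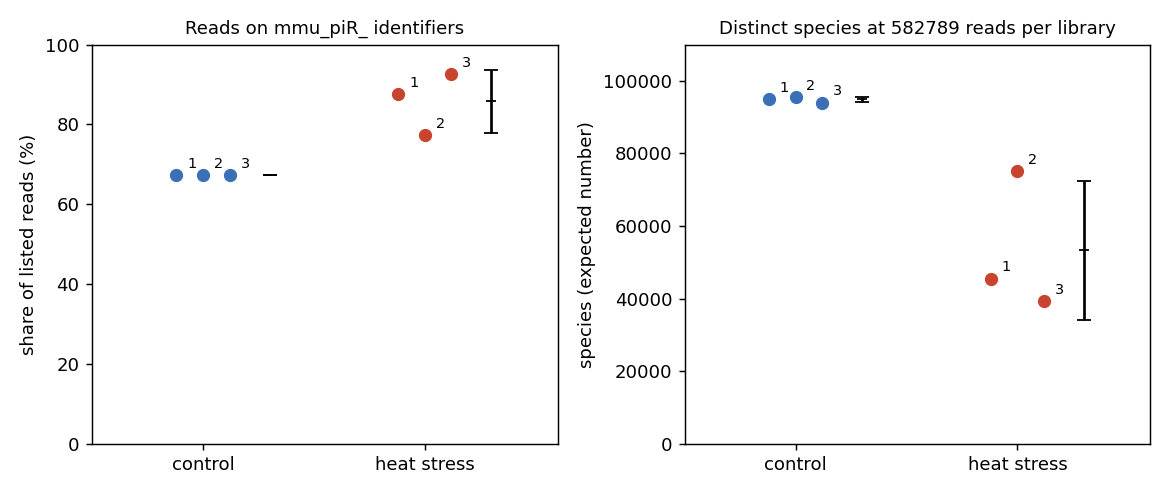
Share of listed reads on mmu_piR_ identifiers in percent (left) and expected number of distinct species at 582789 reads (right), for control and heat stress libraries. Each point is 1 library with its replicate number and the black mark is the group mean with its SD (n = 3); heat stress libraries lie above the controls on the left, at 77.2% to 92.6%, and below them on the right, at 39371 to 75139.

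The main comparison tested each small RNA species between heat stress and control. Of 50786 species, 3228 rose and 16046 fell after heat stress at an adjusted p under 0.05 (limma), and the others did not pass. The 2 types differed in their calls. Among 17626 mmu_piR_ species, 2807 rose, 1737 fell and 13082 did not pass, with a median log2 fold change of 0.03 on the RPM scale. Among 33160 uniq_ species, 421 rose, 14309 fell and 18430 did not pass, with a median of -1.17. The filter can admit a species through 1 group alone. In the files, 22686 uniq_ species had reads in all controls and no heat stress library, against 189 the other way. This selection can lower the median and add falls among low species. Of the uniq_ species tested, 30501 had a mean under 10 RPM, and 12560 of these fell. The species that rose held 51.4%, 23.1% and 42.2% of the reads of heat stress replicates 1, 2 and 3, and 5.50% to 6.07% of the reads of the controls. The species that fell held 6.36%, 18.1% and 7.37% of the heat stress reads and 35.8% to 37.0% of the control reads. These sets were chosen on the same libraries, so the shares are not independent evidence of the change. At species with a mean of at least 10 RPM the groups did not overlap for 58.6%, with heat stress above at 2442 and below at 3851 of 10747 species. Chance gives 10% for 1 species, but all species share the same libraries and their scaling. A shift of whole libraries on the RPM scale separates many species at once, so the 58.6% is not a count of separate changes beyond chance.

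The balance between rises and falls depended on how libraries were scaled and weighted. The median log2 fold change of all tested species was -0.87 on the deposited RPM scale and -0.53 after TMM scaling. TMM adjusts for changes in composition on the assumption that most species are unchanged, which was not tested here. With TMM scaling limma called 4361 rises and 8077 falls, and edgeR's quasi-likelihood test on the recovered reads called 6171 rises and 5445 falls. Among mmu_piR_ species rises outnumbered falls on the RPM scale with equal weights and with TMM (3853 against 550), but not with array weights on the RPM scale (3701 against 3723) or when values were scaled to the mmu_piR_ reads alone (1780 against 1899). Without heat stress replicate 2 they were near balance on the RPM scale, at 3585 rises and 3531 falls. Their median log2 fold change was 0.50 with TMM and -0.26 when scaled to the mmu_piR_ reads. Among uniq_ species falls outnumbered rises on both scales, by 7527 to 508 with TMM, with a median of -0.86. Of the 3228 species that rose, 3100 were also called higher by limma with TMM, by edgeR and by DESeq2, while of the 16046 that fell 3752 were called lower in these fits, whose scaling moves all species upward relative to the RPM scale, which by itself favours keeping rises over falls. On the RPM scale neither direction was kept more often throughout. Without heat stress replicate 1, 69.8% of the rises and 42.3% of the falls were kept, without replicate 3 78.9% and 58.5%, and after thinning 45.0% and 19.4%. With array weights 97.4% and 98.8% were kept, and without replicate 2 94.6% and 98.2%. No species called in one direction was called in the other in any of these fits. The number of changed species was 10954, 11253 and 11763 without control replicates 1, 2 and 3. It was 9375 without heat stress replicate 1, 29512 without replicate 2 and 13106 without the shallow replicate 3, where 2903 rose and 10203 fell. When all libraries were thinned to equal depth, 1492 rose and 3239 fell.

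**Figure D2:**
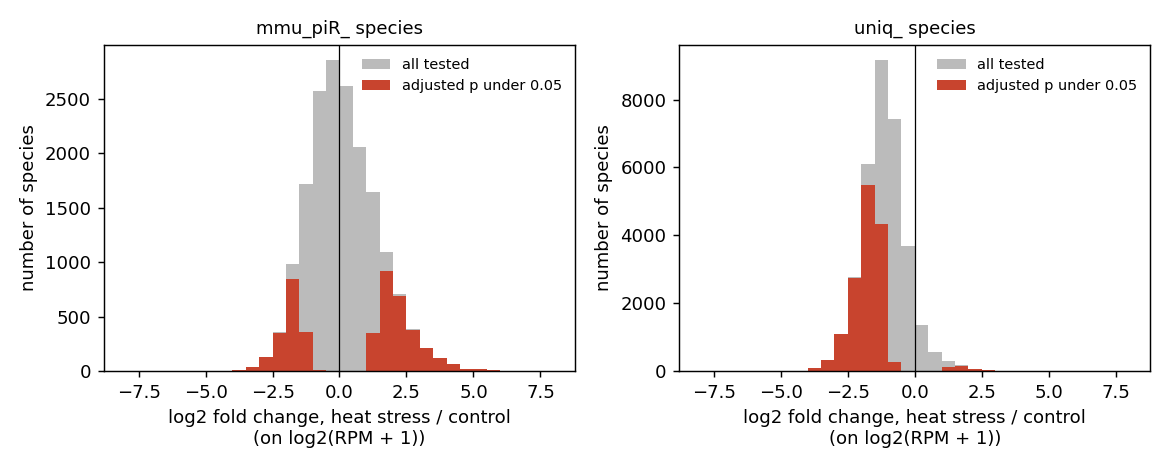
Number of species (vertical axis) by fitted log2 fold change of heat stress over control on log2(RPM + 1) (horizontal axis), for mmu_piR_ species (left) and uniq_ species (right). Grey bars are all tested species and red bars those with an adjusted p under 0.05; mmu_piR_ species are spread on both sides of 0, with a median of 0.03 (-0.26 when scaled to the mmu_piR_ reads alone), and uniq_ species lie mostly below 0, with a median of -1.17.

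On the RPM scale, changes were seen in each tier of abundance. The tiers were set by the mean over the 6 libraries, so a large change can itself move a species to another tier. Of 55 mmu_piR_ species with a mean of at least 1000 RPM over the 6 libraries, 23 rose and 15 fell. Of 1421 between 100 and 1000 RPM, 383 rose and 268 fell. Of 6612 between 10 and 100 RPM, 1274 rose and 782 fell. Among uniq_ species the fall held in the 3 tiers below 1000 RPM: of 97 species between 100 and 1000 RPM 69 fell and 6 rose, with a median log2 fold change of -1.85, and of 2560 species between 10 and 100 RPM 1680 fell and 59 rose, with a median of -1.89. Of 30501 uniq_ species under 10 RPM, 12560 fell and 354 rose. The 2 uniq_ species above 1000 RPM, named here after their values were seen, went the other way, though uniq_344681 would lie in the tier below by its control mean. uniq_344681 rose from 366 ± 75.5 RPM (SD, n = 3) in control to 9730 ± 7733 RPM in heat stress, and uniq_345532 from 1794 ± 535 to 6644 ± 2316 RPM, with all 3 heat stress libraries above the controls (limma log2 fold changes 4.45, SE 0.50, and 1.86, SE 0.40, adjusted p 0.000253 and 0.0051).

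Of the 10 species with the largest rises, 9 were mmu_piR_ species, all 10 were higher in each heat stress library than in every control, and their log2 fold changes lay between 5.77 and 7.82 (limma SE 0.42 to 0.78, adjusted p 6.4e-07 to 0.000559). mmu_piR_023231 had the largest change in the main test, 7.82, but not by the ratio of means or in every alternative. The change of mmu_piR_027073 was larger with a pseudocount of 0.1 (9.04 against 7.84) and with array weights (8.59 against 8.27). It was also larger without heat stress replicate 2 (8.54 against 8.25), with DESeq2 (9.83 against 8.59) and with edgeR (9.09 against 7.99 with total counts). mmu_piR_023231 stood at 73.2 ± 9.62 RPM (SD, n = 3) in control and at 18668 ± 10544 RPM in heat stress, a 255-fold higher mean, and was the most abundant species of heat stress replicates 1 and 3. mmu_piR_038322 rose from 145.7 ± 33.5 to 9397 ± 3854 RPM, a 64.5-fold higher mean. mmu_piR_011571 went from 18.3 ± 1.11 to 2192 ± 2968 RPM, with 5618 RPM in heat stress replicate 1 and 561 and 398 RPM in replicates 2 and 3. mmu_piR_020492 rose from 6.69 ± 3.34 to 582 ± 265 RPM and mmu_piR_037303 from 4.61 ± 0.488 to 453 ± 334 RPM. mmu_piR_013748 rose from 2.58 ± 0.684 to 288 ± 229 RPM. The other 4 were nearly absent from the controls. mmu_piR_027073 stood at 1.04 ± 0.979 RPM in control and 556 ± 571 RPM in heat stress, and mmu_piR_007541 at 0.945 ± 0.607 and 138 ± 128 RPM. mmu_piR_024995 stood at 0.855 ± 0.663 and 102 ± 41.1 RPM, and uniq_301642 at 0.728 ± 0.706 and 297 ± 274 RPM. Several of these heat stress means rested on 1 library. Without heat stress replicate 1 they were 479 RPM for mmu_piR_011571, 240.2 RPM for mmu_piR_027073, 141.1 RPM for uniq_301642 and 64.6 RPM for mmu_piR_007541, and without replicate 3 they were 264.3 RPM for mmu_piR_037303 and 163.1 RPM for mmu_piR_013748.

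Of the 10 species with the largest falls, 8 were uniq_ species, with log2 fold changes between -4.74 and -4.17 (limma SE 0.50 to 0.74, adjusted p 0.000366 to 0.00326). The most abundant of them was mmu_piR_032367, at 243 ± 73.6 RPM (SD, n = 3) in control and 11.98 ± 6.63 RPM in heat stress, a 20.3-fold lower mean. mmu_piR_025935 fell from 33.2 ± 8.61 to 0.532 ± 0.582 RPM, which is 4 reads over the 3 heat stress libraries. uniq_55881 had no read among the 5442494 reads of the heat stress libraries and stood at 25.6 ± 21.2 RPM in control, so that its mean was at least 46.5-fold lower after heat stress against a limit of 3 reads over the group. This bound was 24.2-fold without control replicate 3, which held most of the control signal, and 27.2-fold and 24.3-fold without heat stress replicates 1 and 2, which leaves fewer reads. uniq_450619 stood at 27.6 ± 4.49 RPM in control and at 0.295 ± 0.511 RPM in heat stress. uniq_615155 fell from 53.0 ± 47.0 to 1.03 ± 1.78 RPM, uniq_606122 from 51.0 ± 13.3 to 2.69 ± 4.66 RPM and uniq_530502 from 62.7 ± 54.2 to 2.23 ± 2.64 RPM. uniq_396281 fell from 45.8 ± 12.9 to 3.10 ± 4.99 RPM, uniq_225499 from 43.5 ± 9.46 to 1.78 ± 1.54 RPM and uniq_223390 from 93.4 ± 76.0 to 4.37 ± 4.55 RPM. Part of this spread came from control replicate 3, where uniq_615155, uniq_55881, uniq_530502 and uniq_223390 stood at 107.2, 50.1, 124.7 and 181.1 RPM, against 12.4 to 52.9 RPM in the other controls. In the heat stress group, replicate 2 held the only reads of uniq_615155 (3.08 RPM) and uniq_606122 (8.08 RPM). It also held most of those of uniq_396281 (8.85 RPM, against 0.442 and 0 RPM), uniq_223390 (9.62 RPM, against 1.77 and 1.72 RPM) and mmu_piR_025935 (1.15 RPM, against 0.442 and 0 RPM). The only reads of uniq_450619 lay in replicate 1 (0.885 RPM). For uniq_530502 replicate 3 had the highest value (5.15 RPM, against 0 and 1.54 RPM), but from only 3 of its 7 heat stress reads.

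The species with the highest means over all libraries changed less, except mmu_piR_023231. mmu_piR_021137, the most abundant species in each control library, fell from 21439 ± 1143 RPM (SD, n = 3) to 9851 ± 6659 RPM (limma log2 fold change -1.34, SE 0.43, adjusted p = 0.025). mmu_piR_024946 fell from 10264 ± 229 to 4730 ± 3343 RPM (-1.34, SE 0.43, limma adjusted p = 0.0262). Each was lower in all 3 heat stress libraries than in every control, but with TMM scaling the limma log2 fold changes were -0.72 and -0.72, with adjusted p of 0.168 and 0.192. Without 1 of the controls the limma adjusted p was 0.0569 to 0.0748 with fold changes much as before, -1.37 to -1.29 for mmu_piR_021137 and -1.35 to -1.32 for mmu_piR_024946. Without heat stress replicate 1 the log2 fold changes were -0.91 and -1.01, and without replicate 3 -1.25 and -1.12, with limma adjusted p of 0.0827 to 0.107. Without replicate 2 they were -1.85 and -1.88, with limma adjusted p of 0.00386 and 0.0033. Over all settings the adjusted p of limma, edgeR and DESeq2 ranged from 8.17e-05 to 0.384 for mmu_piR_021137 and from 0.000125 to 0.428 for mmu_piR_024946. mmu_piR_026888 stood at 6330 ± 2340 RPM in control and 9499 ± 1727 RPM in heat stress, and mmu_piR_012747 at 7250 ± 526 and 4978 ± 2692 RPM. Neither passed the test, with limma adjusted p of 0.181 and 0.193. Array weights gave 0.0176 and 0.00467 and TMM scaling 0.0491 and 0.812, within ranges over all settings of 0.0176 to 0.626 and 0.00467 to 0.940.

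**Figure D3:**
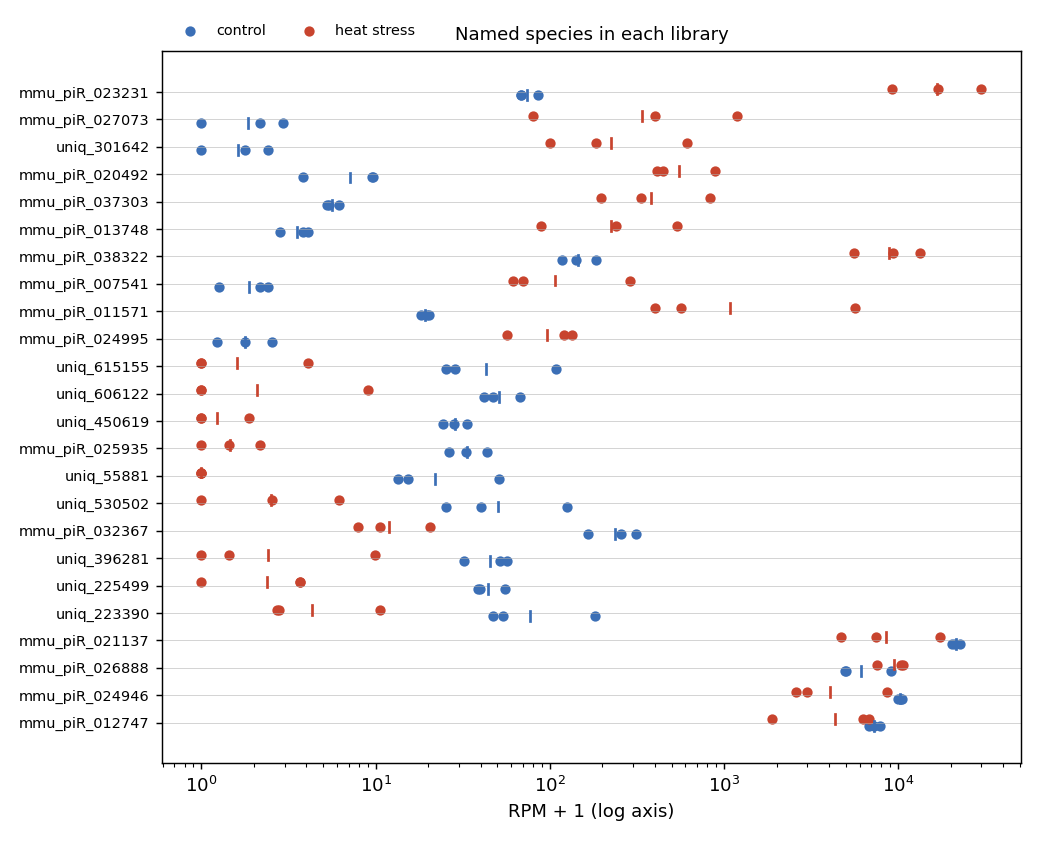
RPM + 1 on a log axis (horizontal) of the named species (vertical) in each library, with control libraries in blue and heat stress libraries in red. Points are libraries and vertical ticks the mean of log2(RPM + 1) of 3 libraries; the 10 upper species rose, with mmu_piR_023231 at 18668 RPM the highest mean in heat stress, the next 10 fell, and the lowest 4 are the other species of highest mean abundance.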

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

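The settings with TMM scaling, with DESeq2 factors on the RPM values, with array weights, with scaling to the mmu_piR_ reads, with thinning and with distinct species at equal depth were chosen after seeing the data. The direction of the 20 species chosen for the largest changes was kept, and each passed the threshold in every alternative that gave an adjusted p (198 values for rises and 192 for falls). Among these values, those of the 2-fold minimum repeat the adjusted p of the main test and add no separate test. DESeq2 gave no adjusted p for mmu_piR_011571, whose heat stress mean rested on 1 library. For this species edgeR gave adjusted p of 0.0369 with DESeq2 factors, 0.0379 with TMM and 7.09e-23 with total counts. The share of reads on mmu_piR_ species differed in the same direction by 20.1 percentage points without the 10 most abundant species and by 15.1 to 22.8 points when each library was left out. Their share of distinct species differed by 17.7 points, but at unequal depth, which by itself raises it in shallow libraries, and by 17.0 points at equal depth (33.9% against 16.8%). That depth was equal over all listed reads, not within each type, so the share of distinct species partly follows the share of reads. The counts of called species moved more, and the cause was not tested. Against 19274 changed species (3228 rose, 16046 fell, of which 2807 and 1737 mmu_piR_ species), the numbers in the same order were 3570 (1144, 2426; 1005, 248) with no filter, 10360 with a pseudocount of 0.1 (2266, 8094; 2023, 902), and 4911 (1649, 3262; 1595, 1100) with at least 10 RPM in 3 libraries, where only 11532 species were tested. With TMM on the RPM values they were 12438 (4361, 8077; 3853, 550), with DESeq2 factors on the RPM values 16333 (3940, 12393; 3444, 1100), with array weights 28921 (4275, 24646; 3701, 3723), and with thinning to equal depth, which leaves fewer reads, 4731 (1492, 3239; 1386, 573). On the recovered reads edgeR gave 11616 (6171, 5445; 5143, 415) with TMM, 14119 (5254, 8865; 4411, 824) with DESeq2 factors and 15259 (3933, 11326; 3331, 1243) with total counts, and DESeq2 gave 9361 (4528, 4833; 3956, 733). Scaled to the mmu_piR_ reads, 1780 mmu_piR_ species rose and 1899 fell. A 2-fold minimum left 18999. Leaving out 1 library gave 9375 to 29512 changed species, 1821 to 4025 rises, 6911 to 25487 falls, 1602 to 3585 mmu_piR_ rises and 714 to 3531 mmu_piR_ falls. The highest number came without heat stress replicate 2 (29512) and the lowest without heat stress replicate 1 (9375); without control replicates 1, 2 and 3 it was 10954, 11253 and 11763, and without heat stress replicate 3 it was 13106. No pairing by replicate number was seen, though one in the design is not excluded. The deviations of libraries with the same number correlated at -0.02, 0.01 and 0.02 across species. Heat stress replicates 2 and 3 correlated best with their own number and replicate 1 did not, but all values lay between -0.03 and 0.03. With the replicate number as a block 21197 species changed (3359 rose, 17838 fell). Depth limits the low species, since 1 read of heat stress replicate 3 is worth 1.72 RPM. The alternatives for length classes, first base, genomic windows, host genes and fixed lists were not run, as the files hold no sequences, lengths or positions and no listed member.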

Other observations

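The search for species found in 1 group only, the tests of dilution and the second test of a mix were chosen after the data were seen, and the other tests below before their results. Some small RNA species were found in 1 group only. Of 303 species with reads in all 3 heat stress libraries and in no control library, 114 were mmu_piR_ species, and 11 had a mean of at least 10 RPM in heat stress. The highest of them, named after its values were seen, was mmu_piR_036218, with 98, 61 and 47 reads in heat stress replicates 1, 2 and 3 (49.2 ± 29.03 RPM, SD, n = 3). Against a limit of 3 reads over the 10702014 control reads, its mean was at least 175-fold higher, a bound that falls to 112-fold without control replicate 1 and 105.6-fold without control replicate 2, which leave fewer reads. mmu_piR_017683 followed among the mmu_piR_ species, with 24.7 ± 15.2 RPM and at least 88.2-fold (56.3-fold and 53.1-fold without control replicates 1 and 2). In the other direction, 22928 species had reads in all 3 control libraries and in no heat stress library, of which 22686 were uniq_ species and 4 reached a mean of 10 RPM. The control libraries hold more reads, which by itself makes such species more frequent among them. Beside uniq_55881, these 4 were uniq_935483 at 17.9 ± 3.67 RPM, uniq_139945 at 15.3 ± 2.48 RPM and uniq_1089099 at 10.5 ± 3.50 RPM in control.

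The real grouping gave 19274 changed species, and the highest of the other splits of the 6 libraries gave 20. Every other split mixes heat stress and control libraries, so any difference between the groups widens the spread there and lowers the calls. The 20 is therefore not a count of false calls. Only 1 of the 10 splits reached the real value, but 10 splits are too few for a share under 0.05.

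The larger share of reads on mmu_piR_ species in heat stress may have a technical origin: lower depth, which hides rare species, is argued against by the species with reads in all 6 libraries, where the share still differed by 8.73 percentage points, with 87.5% to 95.2% in heat stress and 82.8% to 83.1% in control. Over all listed species the difference was 18.5 percentage points, and choosing species by their reads in every library may itself narrow it. A few abundant species taking the reads are argued against as well, since without the 100 most abundant mmu_piR_ species the difference was 20.7 percentage points. What stays open includes heat stress itself, a library preparation that differed with the group, and the unknown rule by which the authors separated the types. Other causes were not tested.

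The species that fell could be an unchanged pool that was diluted by other small RNAs, in which case all would fall by 1 factor. The measure was the gap between the 5th and the 50th percentile of the log2 ratio to the control mean (for a control library, the mean of the other controls). Over the 168 uniq_ species of at least 100 RPM in the controls, this gap was wider than counting error by 1.504 and 1.27 in heat stress replicates 1 and 2, against 0.796 in the most variable control. Over 1253 mmu_piR_ species of the same abundance the excess was 1.84, 1.21 and 1.65 in heat stress replicates 1, 2 and 3, against 0.572 at most in a control. The medians in heat stress replicates 1, 2 and 3 were -1.29, -0.23 and -0.85 for these and -2.49, -0.68 and -2.62 for the uniq_ species. In the control libraries the medians of either type lay between -0.01 and 0.09. A factor common to both types would give like medians, so these values argue against it at this abundance. Within a type, a common factor with no more than the spread of the controls would not give the wider gaps above. However, the heat stress libraries also differed more among themselves, with a median standard deviation of 0.84 on the log2 scale against 0.23 in control. That value also holds shifts of whole libraries, which the gap within 1 library does not, so the measures are unlike. Whether a common factor with a wider spread would give such gaps was not tested. The gaps therefore cannot decide on a common factor within either type. For the uniq_ species of heat stress replicate 3 the excess was 0.739, below the control value, so dilution and unequal loss cannot be told apart for them at this depth either. The uniq_ test was first run at 20 RPM, with excesses of 1.39, 1.19 and 0.291 in heat stress replicates 1, 2 and 3 and 0.309 to 0.640 in the controls; it was moved to 100 RPM, and divided by replicate, after these were seen, because counting error alone gave a gap of 2.75 in replicate 3.

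Heat stress replicate 2 lay between the controls and the other heat stress libraries. One hypothesis is that it may be a mix of the control profile and that of the others, which would place rises and falls at the same fraction of the way. A first test gave medians of 0.348 of the way for 847 rises and 0.652 for 1669 falls, but it chose and scaled species by the same values of replicates 1 and 3, which lowers the fraction of rises, and it is not used. With species changed at least 4-fold in replicate 1, and replicate 2 compared with replicate 3, the fractions were 0.597 for 1539 rises and 0.643 for 2531 falls, a difference of 0.0457, and with the roles of replicates 1 and 3 exchanged they were 0.618 and 0.620. A mix would give such like fractions for rises and falls, but a uniformly weaker response to heat stress would give them too. The share of reads on mmu_piR_ species, which was not part of this test, placed replicate 2 nearer the controls. It was 77.2% there, against 67.3% in control and 87.5% and 92.6% in heat stress replicates 1 and 3. A simple mix would place this share at the same fraction of the way, past the middle, which it did not reach. Both explanations stay undecided.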
